A study of Mus musculus with 10 samples.

How the data were processed

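RNA was measured in the gastrocnemius, a calf muscle, of 10 male mice aged 7.5 months on a C57BL/6 background. Per the labels' protocols, all animals carried a tamoxifen-inducible Cre recombinase transgene and received 8 tamoxifen injections beginning at 4 months of age. In 5 of them the myostatin gene (Mstn) was flanked by the sites that Cre recombines, and these form the knockout group. The other 5 had normal myostatin genes and form the control group. Per the labels, RNA was extracted with Trizol and biotinylated cDNA was made with NuGEN kits.

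The deposited table holds a linear microarray intensity for 45101 probe sets in each of the 10 arrays. Per the submitters' processing notes the values were made with GCRMA, a method that corrects background from probe sequence, normalizes between arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here, and scanner files were not used here. GCRMA leaves dim probe sets in a narrow band near a floor, so differences there are compressed or unstable. The lowest intensity on an array was between 3.57 and 3.77. The log2 of the deposited intensity was taken here and no other normalization was applied. Arrays have no read depth, so the number of arrays limits the precision.

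Probe sets were named from the platform annotation, in which 34958 carried 1 gene symbol, 932 carried several and 9211 were not listed. Probe sets with several symbols were never used for a named gene. Gene identifiers were matched to the GRCm38.p6 gene table, which was used only for names and for gene order, and no symbol changed. No probe set carried the name Mstn in the annotation, so the myostatin transcript is not analysed here and the genotype labels have no check from it.

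Probe sets with a mean log2 intensity of 4 or more over all arrays were kept, and 64 array control probe sets were left out, which left 21154 probe sets for 10704 genes. Knockout and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05 on the adjusted p. Where a gene had several probe sets, the brightest over all arrays represented it. Gene lists (33, holding 753 entries, of which 682 matched) were fixed before the data were examined. The 32 lists with at least 5 measured members were tested with camera in limma at its preset correlation of 0.01, adjusted over lists. The list of blood and erythroid genes had too few. List means per array were also compared by exact permutation over all 252 assignments, for which the smallest possible p is 0.00794. Adjusted over 32 lists, no list can pass by this test alone, without others near that smallest p.

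Genes named in the text follow a rule fixed before the data were examined, apart from genes marked as named after their values were seen and genes added under other observations. The 10 largest rises and 10 largest falls past the threshold with non-overlapping groups were taken. Where fewer passed, the genes of lowest p with non-overlapping groups filled each set and are described as not past the threshold. Up to 4 members of lowest p were added for each list past its threshold or holding a called member. Symbols of unnamed transcripts were skipped. The values of 1 gene that the rule takes are not reported here.

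The fit was tested on simulated data made from the real means and residuals of these 21154 probe sets, with 200 probe sets changed in each of 20 draws. Changes of 0.5, 1, 2 and 3 on the log2 scale were called in 23.5%, 65.2%, 90.4% and 96.3% of cases, and 2.72% of calls were false. The draws gave 142 calls on average and the real fit 21, and the adjustment is stricter where fewer probe sets differ. Another split of the real arrays gave up to 1403 calls. The recovery and false call rates therefore do not carry over to the calls reported here. A list of 30 randomly drawn probe sets lowered by 0.5 was called (camera, unadjusted p under 0.05) in 100% of draws and an unchanged one in 0%. Random lists lack the correlation between members that real lists have, so these rates do not carry over to the lists tested here.

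Alternatives covered the filter on dim probe sets, quantile normalization, median centring, the variance model, array weights, the replicate number as a block, the choice of probe set per gene, the list test and each array left out in turn. Alternatives added after seeing the data were a covariate for the bacterial hybridisation controls, the removal of the 3 arrays on which those controls were highest, and the removal of genes on the chromosome that carries Mstn. No pair of arrays held identical values, and correlations between arrays over the kept probe sets ran from 0.944 to 0.991. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.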

Results

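Transcripts of gastrocnemius muscle were profiled in 5 mice in which the myostatin gene was deleted in adulthood and in 5 control mice with normal myostatin genes. Myostatin is a secreted protein that limits muscle growth. The comparison asks how gene expression in mature muscle differs once myostatin has been removed. On each array between 46.5% and 47.6% of probe sets lay at or above a log2 intensity of 4. The main axis of variation held 53.6% of the variance of the kept probe sets. It did not part the groups, with an exact permutation p of 0.968 (two-sided, n = 5 per group). It followed the bacterial hybridisation controls (7 probe sets of RNA added to each array), with Pearson's r of 0.968 and Spearman's rho of 0.867 over the 10 arrays. Their permutation p values were 5e-05 and 0.00242, or 0.00015 and 0.00726 after adjustment over the 3 relations computed. Without the 2 arrays farthest from the median of the controls' intensity, r was 0.963. These controls averaged 13.12 ± 0.14 in control mice and 13.15 ± 0.25 in knockouts (log2, SD, n = 5 each, exact permutation p = 0.786).

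**Figure D1:**
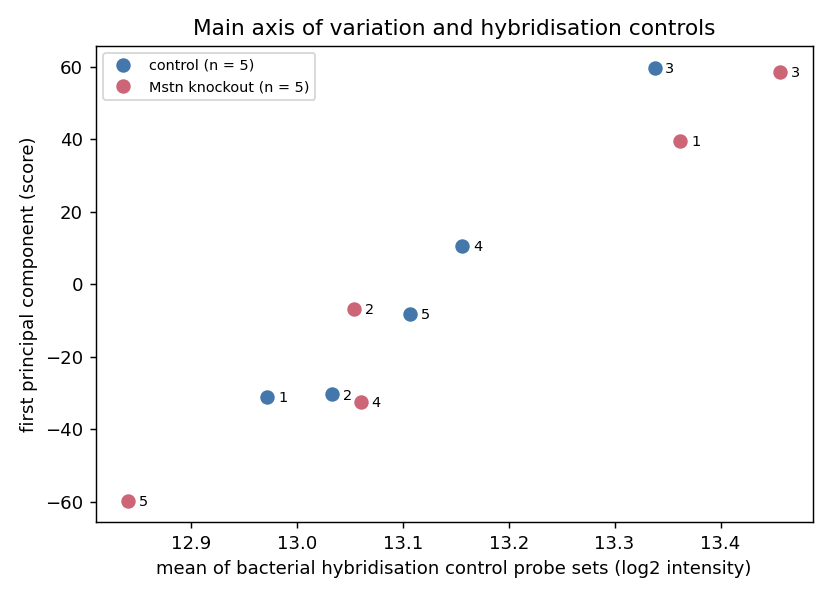
Score of each array on the first principal component (vertical) against the mean log2 intensity of its bacterial hybridisation controls (horizontal), coloured by group and numbered by replicate. Arrays of both groups lie along the same line (r = 0.968 over 10 arrays), with knockout 3, knockout 1 and control 3 highest on the horizontal axis.

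Mettl21e, a methyltransferase-like gene, rose most, from 5.47 ± 0.27 in control muscle to 9.05 ± 0.32 in knockout muscle (log2 intensity, SD, n = 5 each), 11.9-fold, with an adjusted p of 4.72e-05. In all, 21 of 21154 probe sets passed the threshold, 11 higher and 10 lower in knockouts, for 20 genes. At unadjusted p under 0.05 there were 1626 probe sets, where 1057.7 are expected by chance. All 21 had groups that did not overlap, as did 436 probe sets in total (2.06%), where chance gives 0.794%. Both chance values are averages, and probe sets vary together along the main axis, so counts under chance can spread widely around them. Neither count was computed over other splits of the arrays.

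The other named rises past the threshold were Dntt, the DNA polymerase that adds untemplated nucleotides in lymphocyte receptor genes, Wdfy1, an endosomal FYVE-domain protein, Mfsd4a, a predicted transporter, Rasl2-9, a Ran-like GTPase, and Tpd52l1. Dntt differed by 1.92 ± 0.24 (log2, SE, adjusted p = 0.035), but its control mean of 3.30 lay under the filter level of 4. With values below 4 set to 4 its difference was 1.22 and did not pass (adjusted p = 0.0689). Wdfy1 rose 3.26-fold (1.70 ± 0.25 SE, adjusted p = 0.0481), and its other probe sets gave 0.77 and 1.24 without passing. Mfsd4a rose 1.97-fold, Rasl2-9 1.62-fold and Tpd52l1 1.48-fold. The Rasl2-9 value is uncertain because near-identical Ran transcripts could bind its probes. Not past the threshold were Igfbp5, a binding protein of insulin-like growth factors (0.41 ± 0.06, adjusted p = 0.0526), Kcnab1, a potassium channel subunit (0.92, adjusted p = 0.0642), and Tirap, an adaptor of Toll-like receptors (0.45, adjusted p = 0.0769).

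Among the falls, Mss51, a mitochondrial protein gene of skeletal muscle, dropped from 13.12 ± 0.25 to 11.65 ± 0.35, 2.78-fold, with an adjusted p of 0.0297. Junos, an antisense transcript at Jun, was 2.70-fold lower and Cercam, a glycosyltransferase-family gene, 2.50-fold lower. Ramp1, part of the receptor for calcitonin gene-related peptide, was 2.13-fold lower. The collagen genes Col1a2 and Col6a3 were 1.79-fold and 1.47-fold lower. Values not past the threshold were -0.68 for the kinase gene Stk25 (adjusted p = 0.0652) and -1.62 for Prima1, the membrane anchor of acetylcholinesterase, whose knockout mean of 3.36 lay near the floor (adjusted p = 0.0652). Zfp318, Kansl1l and Uxs1 (higher) and Col1a1 and Ddah1 (lower) passed only on a probe set other than their brightest, and are named here after their values were seen. For Kansl1l none of the 4 other probe sets had the same sign, and 1 of them gave -1.51 (adjusted p = 0.513), so its direction is not settled.

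Of the genes named so far, Mettl21e, Wdfy1, Mfsd4a, Igfbp5, Kansl1l, Uxs1, Ramp1, Col6a3 and Stk25 lie on the chromosome that carries Mstn, in the GRCm38.p6 gene order. Mettl21e lies 22 protein-coding genes from Mstn, so a local effect on it is not excluded. Apart from Mettl21e, most calls lay near the threshold: leaving out any of 8 arrays (control 2, 3, 4 or 5, knockout 1, 2, 3 or 4) left 3, 2, 1, 1, 2, 2, 1 and 1 calls in that order. Without the 3 arrays of highest hybridisation controls 5 probe sets passed, with those controls as a covariate 99 passed, and without genes of the Mstn chromosome 7 passed.

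**Figure D2:**
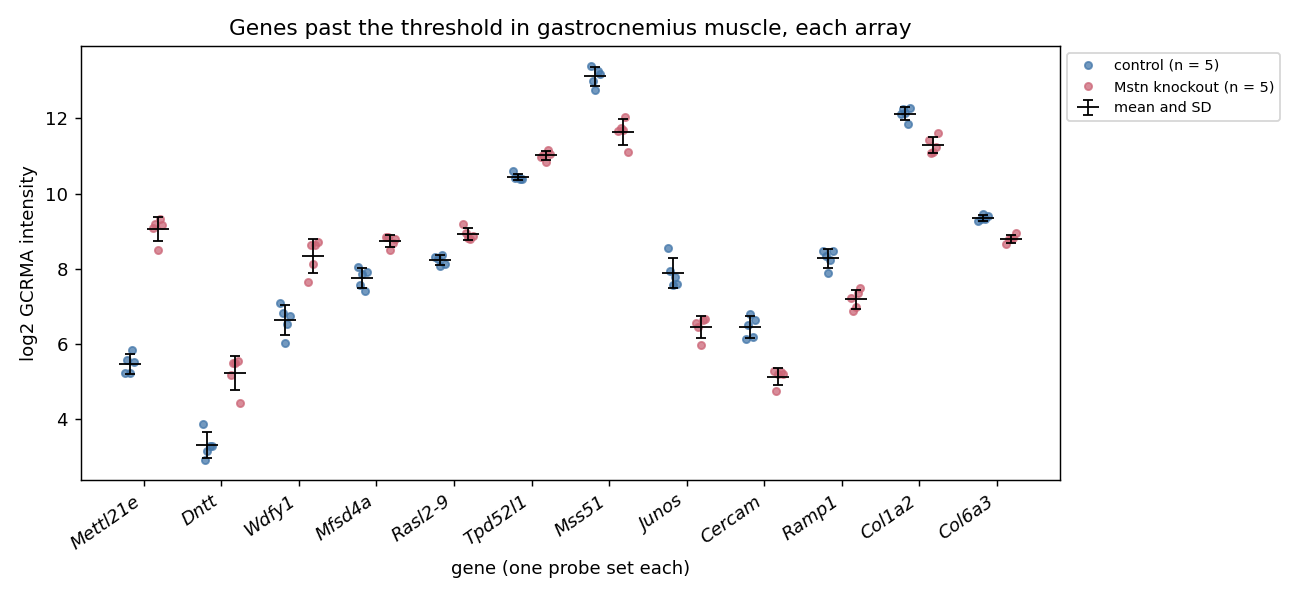
Log2 GCRMA intensity (vertical) of the 12 named genes past the threshold, with a point for each array, control and knockout side by side, and bars for the mean and SD of 5 arrays. The groups do not overlap for any of these genes, and Mettl21e shows the widest gap, 5.47 against 9.05.

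Genes of fibrillar collagen and interstitial matrix, the scaffold between muscle fibres, were lower as a group. All 28 measured members had lower values in knockouts, 2 of them past the threshold over all probe sets and 15 adjusted over the list alone, with a median of -0.51 (log2). The list passed camera with an adjusted p of 2.29e-19, but not with an estimated correlation (adjusted p = 0.344). Its mean per array differed by -0.50 (95% interval -0.82 to -0.18), with an exact permutation p of 0.0159, or 0.381 adjusted over lists. No list could pass that adjustment alone, because the smallest possible p is 0.00794. Col1a2 fell by 0.84 and Col6a3 fell by 0.56, while Col6a1 (-0.40, adjusted p = 0.0691) and Col6a2 (-0.51, adjusted p = 0.0702) did not pass. The basement membrane list, of the sheet around each fibre and vessel, passed camera (14 of 14 members with lower values, median -0.25, adjusted p = 2.33e-06), but not with an estimated correlation (adjusted p = 0.367). None of its members passed singly, and Col4a1 (-0.28), Nid1 (-0.31), Col4a2 (-0.29) and Lama2 (-0.21) had the lowest p.

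Markers of tendon and of 5 types of cell other than muscle fibres were also lower, while adipocyte markers were not (6 of 8 members with higher values, median 0.14, adjusted p = 0.211). The tendon list had a median of -0.90 over 9 members (camera adjusted p = 2.88e-07), and 8 members passed adjusted over the list alone but none over all probe sets. With an estimated correlation its adjusted p was 0.367, and its exact permutation p was 0.0238. Tendon members of lowest p were Thbs4 (-0.81), Fmod (-0.50), Cilp2 (-1.10) and Comp (-1.14). The fibroblast list had a median of -0.41 (adjusted p = 3.15e-05), but an adjusted p of 0.594 with an estimated correlation and an exact permutation p of 0.0476. Its members of lowest p were Mfap5 (-0.60), Cd34 (-0.34), Thy1 (-0.44) and Dpt (-0.42). The Schwann cell list, of the cells that sheathe nerve, had a median of -0.38 over 5 members (adjusted p = 0.00439), but an adjusted p of 0.594 with an estimated correlation and an exact permutation p of 0.0635. Cnp had -0.33, Pmp22 -0.31, Sox10 -0.40 and S100b -0.38. The macrophage list had a median of -0.36 (adjusted p = 0.00171), but an adjusted p of 0.81 with an estimated correlation and an exact permutation p of 0.286. Csf1r had -0.37, Fcer1g -0.46, Laptm5 -0.41 and C1qb -0.35, though another Laptm5 probe set gave 0.24. The smooth muscle list had a median of -0.24 (adjusted p = 0.00286), but an adjusted p of 0.594 with an estimated correlation and an exact permutation p of 0.135. Myh11 had -0.49, Tagln -0.47, Notch3 -0.36 and Acta2 -0.43. The endothelial list, of vessel lining, had a median of -0.19 (adjusted p = 0.00325), but an adjusted p of 0.594 with an estimated correlation and an exact permutation p of 0.127. Tek had -0.27, Ramp2 -0.33, Vwf -0.34 and Egfl7 -0.22. No member of these 5 cell type lists passed over all probe sets. The calls of the smooth muscle, macrophage and Schwann lists were lost without the 3 arrays of highest hybridisation controls (adjusted p = 0.0709, 0.136 and 0.223), Schwann also without control 3 (0.0585) and macrophage without knockout 3 (0.0573). A measure of RNA integrity, the difference between the 3' and 5' Gapdh probe sets, was 0.49 ± 0.03 in controls and 0.45 ± 0.03 in knockouts (SD, n = 5 each, exact permutation p = 0.0317). For beta-actin this difference was 1.47 ± 0.06 in controls and 1.40 ± 0.05 in knockouts (exact permutation p = 0.0873). Neither p is adjusted.

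**Figure D3:**
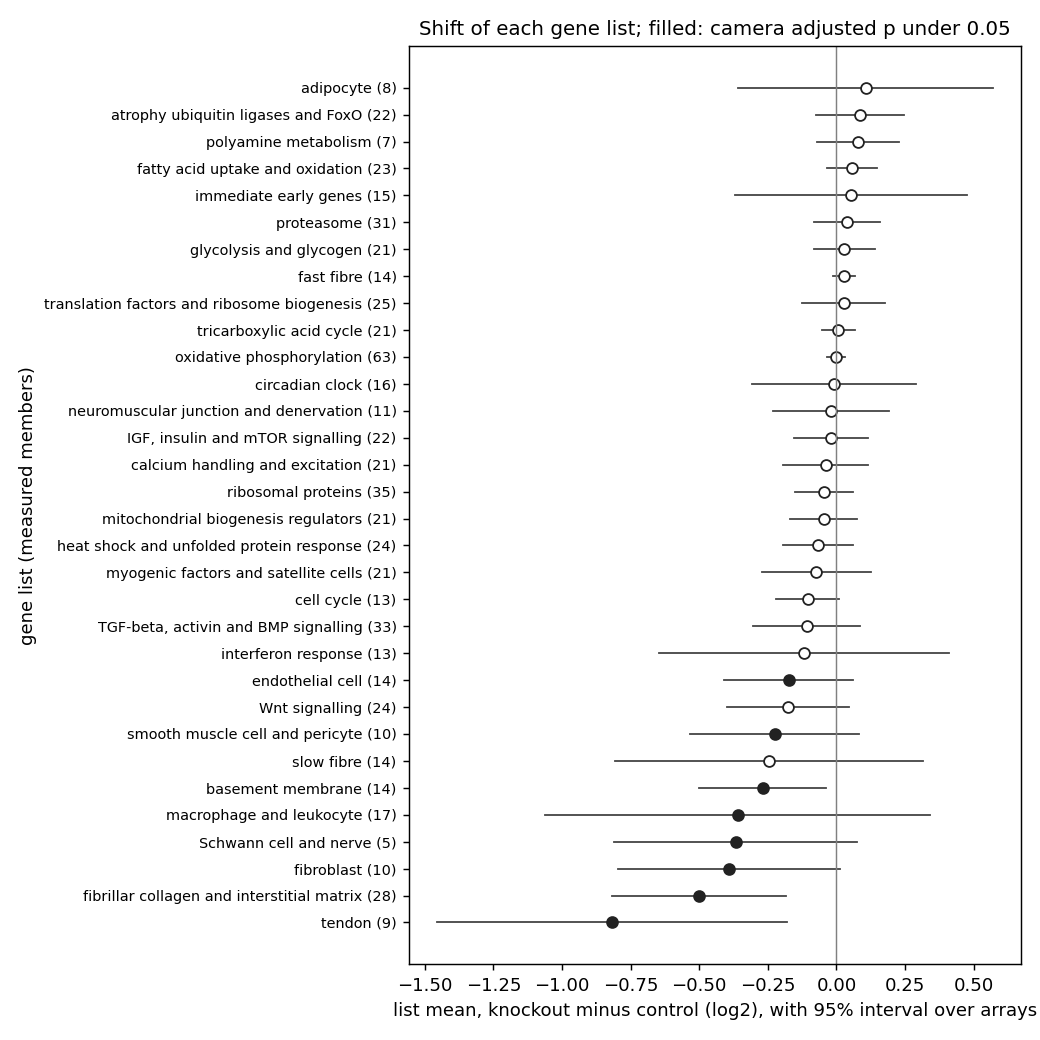
Knockout minus control difference of each gene list's mean (log2, horizontal) with its 95% interval over arrays, for 32 lists with their measured members in brackets. Filled points mark the 8 lists past the camera threshold, all lower in knockouts, from -0.82 for tendon to -0.17 for endothelial cells, and no list passed with an estimated correlation.

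Lists of the muscle fibre itself did not pass. Slow fibre genes had lower values for 13 of 14 members (median -0.26, adjusted p = 0.0933, 95% interval of the mean -0.81 to 0.32). Fast fibre genes had a median of 0.03 (adjusted p = 0.191). Oxidative phosphorylation (63 members) and the tricarboxylic acid cycle had medians of -0.0017 and 0.0077 (adjusted p = 0.818 each). Median member levels of the fast fibre, oxidative phosphorylation and tricarboxylic acid lists were 15.08, 14.06 and 13.44 (log2), where the arrays' maximum was 16.01 to 16.07. Saturation near the top of the scale can compress differences, so these small medians do not show that the genes were unchanged. Fatty acid oxidation had a median of 0.05 (adjusted p = 0.0592) and glycolysis 0.04 (adjusted p = 0.164). Adjusted p was 0.127 for atrophy ligases, 0.169 for the proteasome, 0.139 for ribosomal proteins, 0.505 for translation factors and 0.818 for regulators of mitochondrial biogenesis. It was 0.115 for TGF-beta signalling, 0.449 for Wnt signalling, 0.917 for insulin-like growth factor signalling, 0.658 for myogenic factors and 0.173 for the cell cycle. Polyamine metabolism, calcium handling and the interferon response each had 0.463 and the neuromuscular junction 0.906. Immediate early genes had 0.917, heat shock genes 0.714 and the circadian clock 0.505. The direction given by camera opposed the sign of the list mean for oxidative phosphorylation, insulin-like growth factor signalling, immediate early genes and the circadian clock, none of which passed. For immediate early genes the median (-0.01) and the mean (0.05) also differed in sign.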

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

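The tests of the main axis of variation in this part were chosen after that result was seen, and the test for far-off arrays was set before. Of 162 groups of 5 arrays tested (genes, list means and hybridisation controls), 8 held an array far from its group, where chance gives about 1 in 20, or 8.1. Cercam lay at 4.73 (log2 intensity) in knockout 2, while the other knockouts lay between 5.18 and 5.27. Mettl21e was 8.49 in knockout 3 against 9.09 to 9.33 in the others. Tpd52l1 was 10.60 in control 1 against 10.39 to 10.44. Control 5 was low for Pmp22 (12.25), S100b (4.77) and the Schwann cell list mean (8.68, against 9.23 to 9.37). Control 3 was low for the list means of the proteasome (11.98) and of translation factors (10.70).

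The arrays varied most along an axis that followed the hybridisation controls, with r of 0.968, which held at 0.963 without 2 arrays and at 0.987 and 0.981 within control and knockout arrays. The amount of labelled target on each array is a candidate explanation, since the controls are added in fixed amount and the arrays were normalized to each other. How it would raise the controls was not tested. RNA degradation stays open: r with the 3' to 5' difference of beta-actin was 0.405 (Spearman's rho 0.430, permutation p = 0.244 and 0.217, adjusted 0.367 and 0.263), with a 95% interval from -0.30 to 0.82, but 0.0040 without the 2 arrays farthest from its median, on which it rests. For Gapdh r was 0.319 (rho 0.394, permutation p = 0.376 and 0.263, adjusted likewise), with an interval from -0.39 to 0.79, and 0.426 without 2 arrays. Genotype is argued against as the main cause: 99.9987% of the variance along the axis lay within groups, and the upper 95% limit of the share between groups was 40.1%, while whether both groups lay at each end of the axis depended on counting 2 or 3 arrays there and was not used.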

How the results depend on the processing

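The hybridisation control covariate, the removal of 3 arrays and the removal of genes on the Mstn chromosome were chosen after seeing the data; the rest was set before. Kansl1l reversed with its brightest probe set (-0.15, adjusted p = 0.693) and with the mean of its probe sets (-0.13, adjusted p = 0.886); no other named gene or list past the threshold reversed under the alternatives run. The count of 21 probe sets became 11 with no filter on dim probe sets and 34 after quantile normalization. It was 58 with a variance trend and robust fit and 67 with array weights. It became 99 with the hybridisation control covariate (62 higher and 37 lower, with all 21 kept) and 5 without 3 arrays (2 shared). Without the Mstn chromosome it became 7. Of the called genes 7 lay on that chromosome and 13 elsewhere, so genes elsewhere lost calls too. That setting refits the same values without those genes, so calls elsewhere were lost mainly because the adjustment then ranks fewer low p values. The causes of the other changes were not tested. Median centring gave 28, with 17 higher and 11 lower, against 11 and 10. Each array left out in turn gave 1 to 17 probe sets, and Mettl21e passed in each. With the replicate number as a block 1 probe set and 8 lists passed. Deviations of same-numbered arrays correlated at -0.51, 0.13, 0.62, -0.20 and 0.19, and only control 5 matched its own number best. These correlations cover whole arrays, which vary mostly along the main axis, so they do not settle whether the numbers pair the mice. The count of 8 lists became 0 with an estimated correlation and 0 by exact permutation of list means (3 at unadjusted p under 0.05). The smallest possible p of that permutation keeps any list from passing alone after adjustment, so its 0 is nearly fixed by the design. The count was 1 by fry (the matrix list, adjusted p = 0.0368) and 14 with no filter. It was 0 with the covariate and an estimated correlation (2 at unadjusted p under 0.05). Each array left out gave 8 to 10. Without control 3 the Schwann list lost its call (adjusted p = 0.0585) and 3 others gained one, and without knockout 3 the macrophage list lost its call (adjusted p = 0.0573) and 2 gained one. Without the 3 arrays of highest hybridisation controls 6 lists passed, 5 of them shared: smooth muscle (adjusted p = 0.0709), macrophage (0.136) and Schwann (0.223) lost their calls and slow fibre gained one. The planned test of the Mstn transcript was not run because no probe set carries that name. With values below log2 4 set to 4 the count stayed at 21, 20 of them shared, and Dntt lost its call (1.22, adjusted p = 0.0689). Signal over background limits Dntt and Prima1, whose means lie near the floor in 1 group.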

Other observations

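The tests of the Mstn chromosome, of equal dilution and of labelled target were chosen after the results were seen, and those of gene lists, of other splits of the arrays and of tendon tissue before. Some members of lists that did not pass differed when adjusted over the list alone, though none passed over all probe sets. These genes fall outside the naming rule fixed beforehand, and this adjustment does not cover the number of lists. Fbxo32, a ubiquitin ligase of muscle atrophy, was 0.47 higher and Gadd45a 0.67 higher (list alone adjusted p = 0.0151 each). The TGF-beta list members Skil (-0.48), Fstl1 (-0.52), Acvr1 (-0.54) and Fst (-0.62), the last a secreted inhibitor of myostatin, each had 0.0286. Myf6, a myogenic transcription factor, was 0.27 higher (0.0227), Odc1, the first enzyme of polyamine synthesis, 0.66 higher (0.0227), and Dkk3 had -2.18 (0.0277).

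In 3 of 100 splits of the arrays 5 against 5, the real one included, at least 21 probe sets passed. Such a count was rare, but other splits gave far higher ones, so it does not exclude chance. The highest other split gave 1403 and another gave 603. Such counts point to a structure of the arrays. Both splits are among the 6 with the widest gap in hybridisation controls (0.25 to 0.29 on the log2 scale, against 0.03 for the real groups). The other 4 of these gave no call, and none of the remaining 93 splits gave more than 1. For gene lists 20 of 100 splits gave at least 8, with 10 the highest other, so chance is not excluded for the count of lists.

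Genes on the chromosome that carries Mstn differed more often: at unadjusted p under 0.001 there were 18 of 631 genes on it (2.85%) and 57 of 10036 elsewhere (0.568%), which chance placement does not explain (Fisher's exact p = 2.46e-07). They lay closer to Mstn in gene order, 201.5 protein-coding genes away on average against 409.1 for the others (permutation p = 0.00347), with 15 in the nearer 306 genes and 3 in the farther 306. DNA carried along with the floxed gene, or another local effect, is a candidate explanation. Mettl21e, which passed with each array left out, lay 22 protein-coding genes from Mstn, so its rise is open to this explanation. Of the 18 genes 66.7% were higher in knockouts (95% exact binomial interval 41% to 86.7%). Other probe sets of Kansl1l, Usp37 and Eif4e2 mostly had the opposite sign, and with these 3 turned 61.1% were higher (35.7% to 82.7%). Weaker probe binding of donor-strain transcripts would lower values in knockouts, so it does not account for the genes that were higher. Whether such transcripts bind some probes more strongly was not tested, so a difference in probe binding stays open for those genes. Weaker binding stays open for the genes that were lower, and the intervals do not settle which are the majority. An effect of myostatin loss itself also stays open.

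Matrix, tendon and most lists of cells outside the fibre were lower together, with the adipocyte list (mean 0.11) as the exception. The 9 lists moved apart (exact permutation p = 0.00794, the smallest possible), but the 8 without adipocytes did not pass (p = 0.0794), so equal dilution of the lower lists stays open. Of the 8 pairs of the matrix with another list, adipocyte (exact permutation p = 0.00794) and endothelial (0.0159) were under 0.05 unadjusted. Adjusted over pairs both had 0.0635. No pair could pass that adjustment alone, so it decides nothing. The groups differed by 0.03 in the hybridisation controls (log2, exact permutation p = 0.786), so a slope on them could remove little. After that slope within groups -0.47 of the -0.50 remained (permutation p = 0.00794), which the small gap nearly fixed in advance. Near-equal controls in the groups argue against the amount of labelled target, and the slope test adds nothing to that. Tendon tissue in the control dissections cannot be told apart from a change in the matrix: after the slope on the tendon list -0.19 remained (permutation p = 0.0397), less than the test asked to set this explanation aside. Both slopes were fitted within the true groups and held fixed in the permutations, so both p values are approximate. The 3' to 5' difference of Gapdh also differed between the groups (exact permutation p = 0.0317, unadjusted) and was not tested against the matrix difference. A lower matrix expression in knockouts may be real, as a hypothesis, with tendon, dilution and RNA integrity left open.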
